A study of Mus musculus with 6 samples.

How the data were processed

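RNA from heart tissue of mice was measured on 6 one-colour arrays, 3 of samples after sham surgery and 3 of samples with myocardial infarction (MI). MI was made by tying off the left anterior descending coronary artery, per the labels' protocols. The time between surgery and sampling is not given in the sources used here. The array was Agilent's mouse ceRNA design in the format of 4 arrays on a slide, with Cy3-labelled cRNA, per the labels' protocols. A ceRNA (competing endogenous RNA) array carries probes for several kinds of RNA, among them circular RNAs. Agilent Feature Extraction was used, per the submitters' processing notes. Its version, the background correction, the normalization and the probe filter are not given in the sources used here.

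The deposited values are log2 intensities, 1 column per array and 65521 rows. In every column they ran from 1.26 to 18.04, a range that a log2 scale of scanner intensities gives. Between 39.2% and 39.7% of the values of an array recurred exactly in another array, taken pair by pair, and the highest value was identical in all 6. Values are shared in this way after quantile normalization over a wider set of features, but the step itself is not recorded in the sources used here. The deposited log2 values were used as already normalized between arrays. The 75th percentiles of the arrays lay within 0.055 of each other, under the limit of 0.2 set for re-centring. Detection flags, slide positions and scan records were not used here.

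Rows were classed by their identifiers. Of these, 11024 name CIRCpedia, a catalogue of circular RNAs, and are called circRNA probes here. Another 54429 begin with mclstr, a prefix whose meaning is not given in the sources used here. The remaining 68 are control features (spike-in probes, grid corners, negative controls, and probes named for GAPDH and PGK1) and were left out of the tests, so that 65453 probes were tested. None of the probe identifiers (0 of 65453) matched any entry of the RefSeq gene table used here, which has 49997 genes. Probes are therefore reported by identifier, and no gene, chromosome or gene list is assigned to them. The planned gene-level tests, gene lists and tests of Cd3d and Trim13 were not run, and those genes are not analysed here.

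The comparison of MI with sham was fitted per probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, group as the only term). Benjamini-Hochberg adjustment ran over all tested probes, and an adjusted p under 0.05 was the threshold. All adjusted p-values below are from limma. Errors are SDs over the 3 arrays of a group, or standard errors (SE) of the limma coefficient. Single quantities, such as a control feature, were compared with a two-sided exact permutation test, which cannot go below p = 0.1 with 3 arrays against 3. The labels call the arrays of a group separate biosamples. Whether each was 1 animal is not stated. The limma p-values set the group difference against the spread between these samples, with the variance moderated over all tested probes. That spread need not be the one between animals.

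In place of detection flags, the highest value of the 2 negative-control features on any array, 2.62 on the log2 scale, served as the background level. It is the dark corner of MI replicate 2, and the other values of these features were 1.80 or lower, which was tried as a lower level after seeing the data. Where any array of the dimmer group lay below background, the fold change is given as a bound. The bound sets the brighter group's mean against the dimmer group's values raised to that level. An adjusted p-value printed beside a bound is from limma on the values as measured and does not test the bound. The circRNA probes as a set were tested with limma's camera (preset correlation 0.01, and again with an estimated correlation). A second contrast set them against mclstr probes of the same level, in 10 bins of mean intensity at a mean of 5 or more. For each MI array, probes were also chosen on the other 5 arrays (limma p under 0.005 without adjustment, mean of 5 or more). The part of the change reached by the array left out was then the median of its own change over the change in the other MI arrays. Its 95% interval came from 1000 bootstrap draws over probes, which are not independent, so the interval is too narrow.

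The limma step was tested on simulated data built from the means and fitted spreads of all 65453 probes. In each of 10 runs 200 probes were changed, all drawn from probes with a mean of 5 or more. Of the changes at these probes, limma recovered 0% of 1.41-fold, 9.0% of 2-fold, 85.0% of 4-fold and 97.8% of 16-fold ones. Of its calls, 3.62% were false. Recovery at dimmer probes, where the spread between replicates was wider, was not tested. Simulated noise need not match that of the arrays, so these rates hold for the simulation only. Recovery depends on how many probes change, because the adjustment is stricter when few do. The number of arrays limits the precision, and no read or count depth applies.

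The tests, the naming rule and the following alternatives were chosen before the data were examined: quantile normalization of the tested probes, centring on the 75th percentile, leaving out probes below the median mean intensity, eBayes with trend and robust settings, replicate number as a block, leaving out each array, and thresholds with a 2-fold minimum. Added after seeing the data were the mclstr counts, the circRNA set test and contrast, the control features, the part of the change reached by each array, and a batch term for MI replicates 2 and 3. The circRNA probes named are the 2 in each direction with the largest fitted change past the threshold, by that rule. The fitted change is not fully measured where a group lies below background, and by their bounds the 2 probes that fell stand in the opposite order. Figures were drawn with matplotlib 3.10.9.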

Results

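Mouse heart RNA was profiled on 6 arrays, 3 of samples from sham surgery and 3 of samples with myocardial infarction (MI). The series' title concerns TRIM13, a ubiquitin ligase of the tripartite motif family, and CD3D, a chain of the T cell receptor complex. The probe identifiers are not paired with genes in the tables used here, and both genes are not analysed here. The array's probes fall into 11024 circRNA probes and 54429 mclstr probes, besides 68 control features. The median over circRNA probes of the mean log2 value was 4.97, and over mclstr probes 2.29. On the 6 arrays, 78.5% to 81.5% of circRNA probes and 46.8% to 47.7% of mclstr probes lay above the background level of 2.62.

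Over the 17974 probes with a mean of 5 or more, Pearson's r between sham arrays ran from 0.993 to 0.995. Between MI arrays it ran from 0.983 to 0.996, lowest between MI replicates 1 and 2, and between groups from 0.964 to 0.974. These correlations are across probes, which are not independent replicates. The spread between replicates depended on level. Among the 24651 probes with a mean under 2, near the lowest value of 1.26, the median SD was 0.15 in sham and 0.25 in MI. Among probes with a mean of 2 to 3, the median SD was 0.65 in sham and 0.67 in MI. Among probes with a mean of 8 to 12 it was 0.067 in sham and 0.092 in MI.

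The comparison of MI with sham asks which transcripts changed in the heart after coronary ligation. MI samples differed from sham samples at 3160 of 65453 probes (4.83%, limma, adjusted p under 0.05), of which 1428 rose and 1732 fell. The rises were the larger changes. With values below background raised to that level, 188 probes rose and 13 fell by at least 4-fold, and 32 rose and 0 fell by at least 16-fold. Among probes with a mean of 5 or more, 99 rose and 4 fell by 4-fold or more, and 23 rose and 0 fell by 16-fold or more. The largest measured rise was 12.58 ± 0.27 (log2, SE), on an mclstr probe with values of 1.43, 1.82 and 1.78 in the sham arrays and 14.60, 13.73 and 14.45 in the MI arrays. Its sham values lay below background, so the rise was at least 3183-fold (limma adjusted p = 0.00044). The probe with the largest fall, also of the mclstr class, stood at 5.62 ± 0.06 in sham and 2.22 ± 0.79 in MI (log2, SD, n = 3), with 2 of its 3 MI arrays below background. It was at least 7.14-fold lower (limma adjusted p = 0.019). These 2 mclstr probes were chosen after their values were seen. Their p-values are from limma on the values as measured and do not test the bounds. The median size of a called change was 0.91 on the log2 scale. The count depended on which array was left out, and the balance of its directions turned whichever array it was. The count was 4535 without MI replicate 1, 1197 without MI replicate 2 and 235 without MI replicate 3. It was 811, 381 and 329 without sham replicates 1, 2 and 3. In each of these 6 fits more probes rose than fell, with 53.5% of calls higher in MI without MI replicate 1 and up to 72.8% without MI replicate 3. With all arrays that share was 45.2%, and 59.0% with a 2-fold minimum on the fitted change. The balance holds for the deposited scale only, since no fit scaled to the spike-in probes was run. Their mean differed between MI and sham by -0.29 (log2).

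Background limited part of the calls. At least 1 sham array was below background at 354 of the probes that rose, and at least 1 MI array at 176 of those that fell. All 3 sham arrays were below background at 267 of the probes that rose, and all 3 MI arrays at 159 of those that fell. At these probes only a bound on the fold is measured. The level of 2.62 is the dark corner of MI replicate 2, and the next highest negative-control value was 1.80. At that level the counts with all 3 arrays below background were 133 and 112, and those with at least 1 were 263 and 156. By at least 4-fold, 231 probes then rose and 20 fell. Among probes with a mean of 5 or more, 932 rose and 1416 fell.

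**Figure D1:**
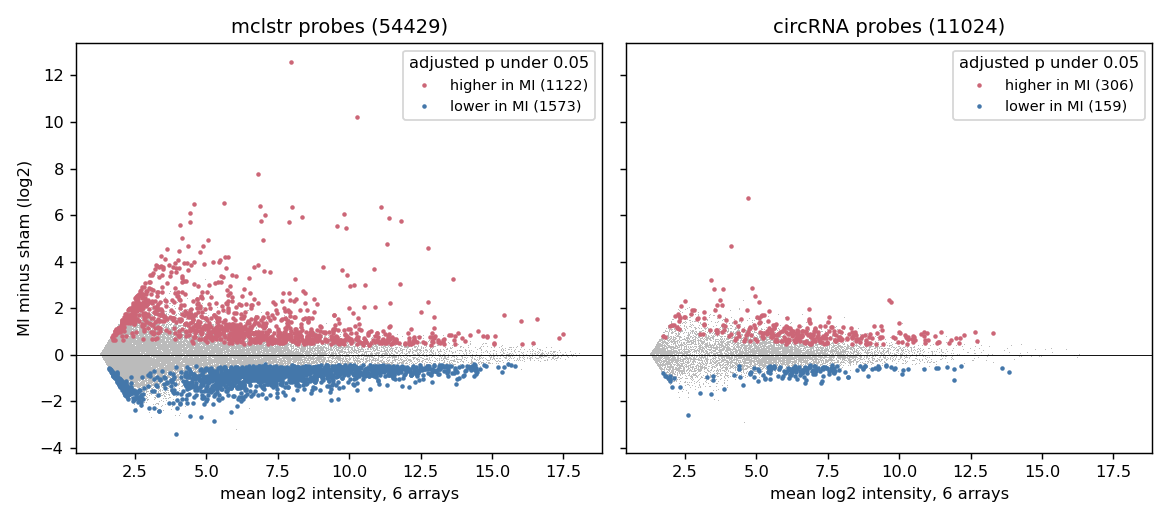
Difference between MI and sham (log2, vertical axis) against mean log2 intensity over 6 arrays (horizontal axis) for mclstr probes (left) and circRNA probes (right). Each point is a probe, coloured where the limma adjusted p was under 0.05. Rises reach further from 0 than falls in both classes, up to 12.58 for mclstr and 6.73 for circRNA probes, with values below background drawn as measured.

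Among circRNA probes, 465 of 11024 passed the threshold (4.22%), with 306 higher and 159 lower in MI. Of mclstr probes 2695 of 54429 passed (4.95%), with 1122 higher and 1573 lower. Higher calls made up 65.8% of circRNA calls and 41.6% of mclstr calls. With single arrays left out, the share of higher calls was 72.5% to 100% for circRNA and 49.4% to 71.3% for mclstr probes. More mclstr probes rose than fell in 5 of these 6 fits, all but that without MI replicate 1. Among probes with a mean of 5 or more the shares were 63.7% and 35.3%. The difference between these shares was not tested itself. Without MI replicates 1, 2 and 3 in turn, 814, 118 and 12 circRNA and 3721, 1079 and 223 mclstr probes passed. Without sham replicates 1, 2 and 3 in turn, 74, 26 and 17 circRNA and 737, 355 and 312 mclstr probes passed. By at least 2-fold, with values below background raised to that level, 99 circRNA probes rose and 16 fell, against 548 and 417 mclstr probes. As a set, the circRNA probes were not shifted against the other probes by the test (camera p = 0.14, and p = 0.21 with an estimated correlation). Without MI replicate 2 the camera p was 0.043. Each probe's mean over the 6 arrays was subtracted before circRNA probes were set against mclstr probes of the same level. The resulting deviations were -0.045 ± 0.040 in sham and 0.053 ± 0.012 in MI (log2, SD, n = 3). Only their difference carries meaning, and they do not show which class was brighter in a group. That difference of 0.097 had p = 0.1 in the exact permutation test, the smallest it can give.

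MMU_CIRCpedia_216148_0_16 rose most among circRNA probes, from 1.34 ± 0.04 in sham to 8.06 ± 0.06 in MI (log2, SD, n = 3). All sham arrays were below background, so the rise was at least 43.5-fold (limma adjusted p = 0.00015). MMU_CIRCpedia_37504_0_9 rose from 1.77 ± 0.47 to 6.44 ± 0.10 (log2, SD, n = 3), at least 14.1-fold (limma adjusted p = 0.0038). MMU_CIRCpedia_7269_16_77 fell from 3.90 ± 0.67 to 1.32 ± 0.03 (log2, SD, n = 3), at least 2.43-fold lower, with all MI arrays below background (limma adjusted p = 0.025). MMU_CIRCpedia_229249_16_18 fell from 4.25 ± 0.14 to 2.56 ± 0.41 (log2, SD, n = 3), at least 2.84-fold lower, with 2 of its 3 MI arrays below background (limma adjusted p = 0.026). These 4 limma p-values are for the changes as measured and do not test the bounds. The SDs of 0.04 in sham for MMU_CIRCpedia_216148_0_16 and 0.03 in MI for MMU_CIRCpedia_7269_16_77 are of values below background. Both rises passed the threshold whichever array was left out. The fall of MMU_CIRCpedia_7269_16_77 passed only without sham replicate 1. That of MMU_CIRCpedia_229249_16_18 passed only without MI replicate 1 or without MI replicate 2.

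**Figure D2:**
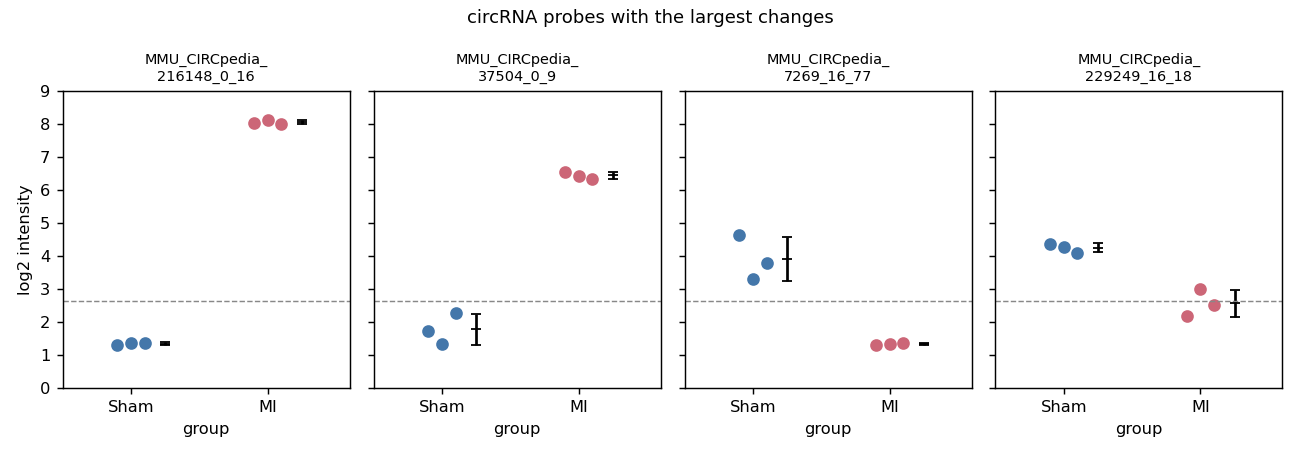
Log2 intensity (vertical axis) of the 4 named circRNA probes in the sham and MI arrays. Each point is an array, the bar beside it the mean ± SD (n = 3), and the dashed line the background level of 2.62. The MI arrays lie between 8.02 and 8.13 for the first probe, whose sham arrays lie between 1.29 and 1.37.

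The fit to all arrays and all 6 fits with an array left out shared 185 probes with the same direction, 143 higher and 42 lower in MI. With values below background raised to that level, 179 of the 185 changed by at least 2-fold. The smallest bound among the 185 was -0.063 (log2). There the brighter group's mean also lay below background, and no fold is measured. Of all 185, 10 were circRNA probes, and all 10 rose.

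MI replicate 1 differed from the other MI arrays at both rises and falls of 2- to 4-fold, more so at rises. Of probes chosen without it, 651 rose 2- to 4-fold in MI replicates 2 and 3, and MI replicate 1 reached a median of 0.25 of that rise (interval 0.19 to 0.29). It moved in the same direction at 71.1% of them. At the 101 probes that rose over 4-fold it reached 1.04 of the rise (1.02 to 1.05), and at the 426 that fell 2- to 4-fold 0.84 of the fall (0.82 to 0.85). MI replicate 2 reached 0.91 and MI replicate 3 reached 0.98 of 2- to 4-fold rises chosen without them (240 and 213 probes). Of 2- to 4-fold falls they reached 1.02 (1.00 to 1.04) and 1.06 (1.04 to 1.07), at 313 and 292 probes. MI replicate 1 itself helped to choose the probes for these values, so the sets of probes differ between the 3 arrays.

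**Figure D3:**
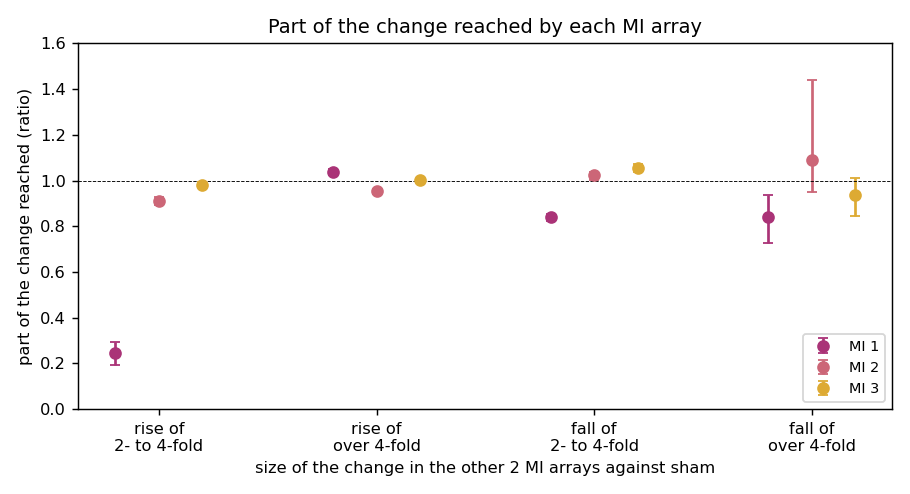
Median part of the change reached by each MI array (vertical axis, ratio) at probes chosen on the other 5 arrays, by direction and size of the change (horizontal axis). Bars are bootstrap 95% intervals over probes, and 1 means the full change. MI replicate 1 lies at 0.25 for rises of 2- to 4-fold and at 1.04 for rises of over 4-fold.

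Among control features are probes with gene names in their identifiers. GAPDH and PGK1 are enzymes of glycolysis, and the array carries probes for each named for mouse, human and rat and ending in 3 or 5. The mouse PGK1 probe ending in 3 stood at 14.74 ± 0.03 in sham and 15.07 ± 0.03 in MI (log2, SD, n = 3, exact permutation p = 0.1). The mouse PGK1 probe ending in 5 stood at 9.67 ± 0.07 and 9.66 ± 0.17 (log2, SD, n = 3, exact permutation p = 0.9). The mouse GAPDH probes ending in 3 and in 5 were each higher in MI by 0.14 (log2, n = 3, exact permutation p = 0.2 and 0.1). The sign of each of these differences was the same under quantile normalization and 75th percentile centring. The 10 E1A spike-in probes, which bind transcripts added to each sample, averaged 9.59 ± 0.04 in sham and 9.30 ± 0.17 in MI (log2, SD, n = 3, exact permutation p = 0.1). The 18 control features named DCP averaged 8.82 ± 0.15 and 8.57 ± 0.10 (log2, SD, n = 3, exact permutation p = 0.1). Both means were lower in every MI array than in every sham array.

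The log2 difference between paired probes ending in 3 and in 5 was higher in MI replicates 2 and 3 than in the other 4 arrays for 4 of the 5 pairs above background. For human-named PGK1 it was 5.93 and 5.91 in MI replicates 2 and 3, and 5.15 to 5.22 in the other 4 arrays. For mouse PGK1 it was 5.51 and 5.49 against 5.03 to 5.25. For rat-named GAPDH it was -2.38 and -2.36 against -3.36 to -2.97. For mouse GAPDH it was 0.19 and 0.20 against -0.01 to 0.19. For human-named GAPDH, the pair without this order, it was 3.46 in all MI arrays and 3.44 to 3.59 in sham. What the endings mark is not given in the sources used here. With MI replicates 2 and 3 given a batch term of their own, chosen after seeing the data, limma called 208 probes, 169 higher and 39 lower in MI. Of these, 147 were among the 3160. This fit rests the comparison on MI replicate 1 against sham.

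**Figure D4:**
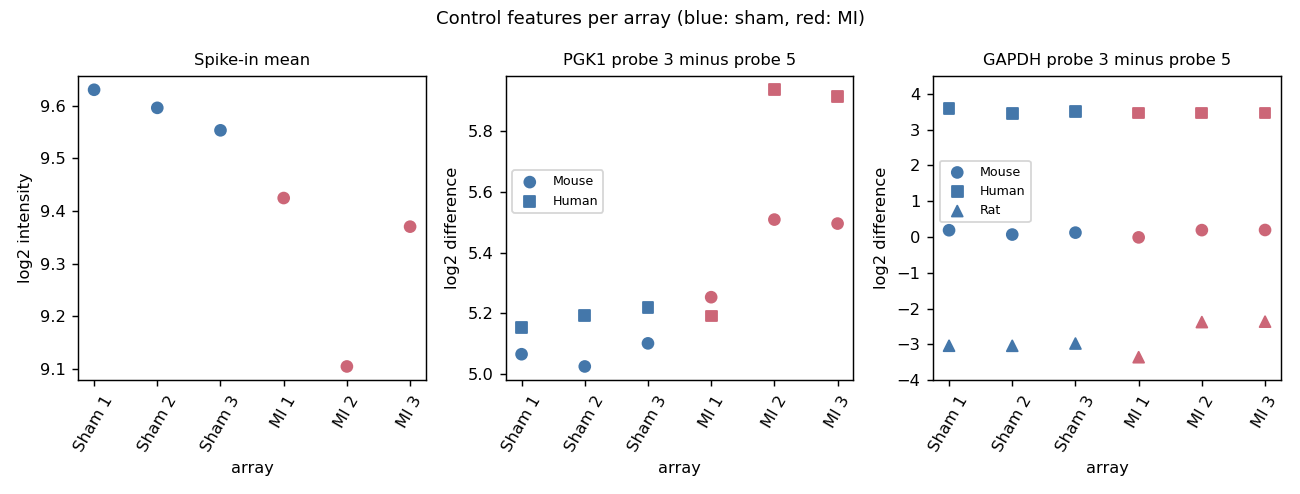
Control features on each array (horizontal axis). The panels show the mean log2 intensity of 10 E1A spike-in probes (left) and the log2 difference between probes ending in 3 and in 5 for PGK1 (middle) and GAPDH (right), with marker shape for the species in the probe's name. MI 2 and MI 3 lie at 5.91 or above for human-named PGK1, and the other 4 arrays at 5.22 or below.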

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

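The control features lie outside the main comparison and were examined after the probe tests. The tests of MI replicate 1 below were chosen after its values were seen; the count over other splits of the arrays was not. Of 23 control quantities, 7 were higher in every MI array than in every sham array and 2 were lower, the means of the E1A spike-in probes (-0.29) and of the DCP features (-0.25). Each has an exact permutation p = 0.1, the smallest that 3 arrays against 3 allow, and the probes of a gene are not independent. For GAPDH the excess in MI was 0.14 for the mouse-named probe ending in 5, 0.15 and 0.20 for the human-named probes ending in 3 and 5, and 0.31 for the rat-named probe ending in 5 (all log2). For PGK1 it was 0.34 for the mouse-named and 0.48 for the human-named probe ending in 3. The difference between the mouse PGK1 probes ending in 3 and 5 was higher by 0.35.

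MI replicate 1 reached only part of the 2- to 4-fold rises seen in MI replicates 2 and 3, with a median of 0.25, and 0.84 of the falls of that size. For rises, a smaller response of one kind in that sample is argued against by those of over 4-fold, of which MI replicate 1 reached 1.04. For falls it is not, since MI replicate 1 reached 0.84 at both sizes. The intervals were 0.82 to 0.85 at 2- to 4-fold and 0.73 to 0.94 at over 4-fold, the latter from 8 probes. A difference in RNA integrity or 3' bias of MI replicates 2 and 3 could account for the pattern of MI replicate 1 and stays open. Of 5 pairs of control probes, 4 set these arrays above the other 4, for 3 of them by more than the range of the others. All pairs are named for GAPDH or PGK1, so they are not independent. For mouse GAPDH, MI replicate 2 stood at 0.194 and sham replicate 1 at 0.191. Human-named GAPDH did not, and the meaning of the endings is not given. A hybridization or slide difference also stays open, since the slides are not given, and the spike-in mean set MI replicates 2 and 3 apart by a gap of 0.26 times the range of the other 4 arrays, and the bright corner by 0.51 times. A biological difference between the MI samples, such as in the tissue sampled or the extent of injury, is untested.

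Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05, and 1 of them, the real one, called as many probes as the real comparison. The real split called 3160 probes (465 circRNA and 2695 mclstr probes), and the highest of the other splits called 0 by limma. At an unadjusted p under 0.05 the real split held 12111 probes and the others 1674 to 3671. Every other split mixes MI and sham arrays in both of its arms, so the difference between the groups adds to its spread. The counts of the other splits were therefore bound to be low and do not measure chance.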

How the results depend on the processing

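The batch term, the lower background level, the mclstr counts and the set test of circRNA probes were chosen after seeing the data; the other alternatives were planned. Counts are given for all, circRNA and mclstr probes, in that order, against 3160, 465 and 2695 in limma with all arrays. Quantile normalization, centring on the 75th percentile and an unadjusted p with a 2-fold minimum kept all 3 counts within 1.5 times, with 2820, 2845 and 1316 of the 3160 probes called again. The arrays were already close in distribution, so quantile normalization and centring alter little and are weak tests of the normalization. A fit scaled to the spike-in probes was not run, so how the counts and their directions depend on that scaling was not tested. The unadjusted rule called 3204 probes, 55.6% of them higher in MI, so its similar count is largely of other probes. Leaving out probes below the median intensity gave 4745 and 856 for all and circRNA probes. The trend and robust variance model gave 5497, 965 and 4532, and 2758 of the 5497 were among the 3160. A 2-fold minimum on the fitted change beside the adjusted p left 1316, 135 and 1181, with 59.0% higher in MI in place of 45.2%. The batch term for MI replicates 2 and 3 gave 208, 18 and 190. With the replicate number as a block, limma called 0, 0 and 0 probes, and 11086, 2089 and 8997 had an unadjusted p under 0.05. No pairing by number was seen. Deviations of same-numbered arrays from their group means correlated across probes at -0.03, -0.10 and -0.01, and no sham array correlated best with its own number. These correlations cannot exclude a pairing, since the deviations within a group of 3 arrays are not independent. The block takes residual degrees of freedom. Leaving out 1 array gave 235 to 4535, 12 to 814 and 223 to 3721 probes, lowest without MI replicate 3 and highest without MI replicate 1. Over all probes, 53.5% to 72.8% of these calls were higher in MI, and 81.2% with the batch term. Fewer arrays leave fewer residual degrees of freedom, and fewer probes a milder adjustment; for the other shifts the cause was not tested. The camera p for circRNA probes ran from 0.043 without MI replicate 2 to 0.31 without MI replicate 3, and was above the threshold under every other setting run. The named circRNA probes kept their direction in every fit run, and under the block none had an adjusted p under 0.05. With the batch term MMU_CIRCpedia_216148_0_16 alone of the 4 did. The gene-level results, gene lists, Cd3d, Trim13 and the mean over probes of a gene were not run, as probes could not be assigned to genes. Changes of dim probes are limited by signal over background. At the lower background level of 1.80 the first 3 named circRNA probes changed by at least 77.0-, 22.5- and 4.29-fold in the order of the text, against 43.5-, 14.1- and 2.43-fold. At that level no array of MMU_CIRCpedia_229249_16_18 lay below background, and it was 3.24-fold lower.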

Other observations

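The comparisons here were all chosen after seeing the data. The third field of an mclstr identifier is a number whose meaning is not given in the sources used here. Over the 12509 mclstr probes with a mean of 5 or more, it correlated across probes with the difference of MI replicates 2 and 3 from MI replicate 1 (Spearman's rho = -0.17). For MI replicates 2 and 3 minus sham rho was -0.075, and for MI replicate 1 minus sham 0.065. At the 829 probes with a value of 50 or less, the median difference from sham was 0.15 in MI replicates 2 and 3 and -0.048 in MI replicate 1 (log2). At the 8481 probes with a value of 51 to 500 it was -0.073 and -0.096. At the 3199 probes with a value over 500 it was -0.096 and -0.015. The median direct difference of MI replicates 2 and 3 from MI replicate 1 was 0.0014 for values of 50 or less, -0.079 for 51 to 500 and -0.13 for values over 500, so the medians against sham do not subtract to it.

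The difference in spike-in level between MI and sham was not uniform. It was -0.57 on the log2 scale for 2 of the 10 E1A probes and -0.13 for the brightest. The dimmest probe lay below background in all 3 sham arrays and in MI replicate 1 and above it in MI replicates 2 and 3, so its difference has no measured size. The mean over the 10 probes, this one included, was -0.29, and -0.32 with centring on the 75th percentile.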
